A study of Rattus norvegicus with 8 samples.

How the data were processed

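Lung RNA from 8 male Sprague-Dawley rats was labelled with biotin from 300 ng of total RNA per sample and hybridised to 1-colour Affymetrix rat expression arrays, and each title calls its sample a biological replicate. Per the submitters' processing notes the values are GCRMA summaries and Partek 6.5 was used. GCRMA corrects background, normalizes the arrays to common quantiles and combines the probes of a probe set. The values the authors deposited are on the log2 scale, as their range of about 1 to 16 shows. Any filter the authors applied to probe sets, any further centring and their test are not given in the sources used here, and no detection calls were used here, so a low value cannot be separated from background. Per-array medians were 7.94 and 7.93 for controls, 7.83, 7.77 and 7.78 for prone, and 7.86, 7.95 and 7.78 for supine replicates 1 to 3.

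Groups were taken from the sample labels: 2 non-ventilated lungs, 3 ventilated prone and 3 ventilated supine, all at high tidal volume. The titles of the supine samples read SVt and those of the prone samples HVt. The condition label gives a high tidal volume for both and was followed, and what SVt stands for is not given in the sources used here. The 28 Affymetrix control probe sets were set aside and used only for RNA quality. Of the other 20214 probe sets, the 16896 at log2 5 or above on at least 2 of the 8 arrays were tested, and 3318 were not. Gene symbols came from GEO's platform annotation and were compared with the RefSeq gene table of the GRCr8 assembly through gene identifiers, which changed 0 symbols. Among tested probe sets 13155 had 1 symbol, 319 several and 3422 none; those with several or none were counted and not named. Genome coordinates were not used here. The probe set with the highest mean over the 8 arrays stood for each of 10240 genes. Of 185 genes the naming rule selected, 31 had several probe sets, and for 3 of them (Tnfaip2, Nedd4 and Sftpb) these were counted as disagreeing. That count does not hold every difference in sign. The 2 probe sets of Kdm5c stood at 1.19 ± 0.28 and -0.20 ± 0.24 in supine against prone lungs.

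A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), leaving 5 residual degrees of freedom and 2.51 prior ones. Tests were two-sided, and a probe set passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors given after ± are the standard errors of this model unless SD is stated. The p-values of this model measure the spread between these samples. Comparisons were prone against control, supine against control and supine against prone. Because the first and second share their controls, their agreement was set against 100 simulations of unchanged groups. Simulations in which arrays of 1 replicate number deviate together, 100 of each kind, were added after seeing the data.

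The comparisons, tests, naming rule, alternatives and 28 gene lists were chosen before the data were examined. 16 lists describe functions: MAP kinase phosphatases, MAP kinase cascade, immediate early transcription factors, cytokines and chemokines, NF-kappaB targets and feedback, stretch and YAP/TAZ targets, heat shock, unfolded protein, glucocorticoid and NRF2 oxidant responses, hypoxia and glycolysis, interferon response, matrix remodelling and coagulation, cell cycle, ion and water transport of lung fluid, and epithelial and endothelial junctions. 12 hold markers of cell types: alveolar type 1 and type 2, airway epithelium, endothelium, neutrophils, macrophages and monocytes, lymphocytes, erythroid cells, fibroblasts, smooth muscle and pericytes, cardiac muscle and mesothelium. They hold 462 genes, of which 376 were tested; the others were not analysed here. The tissue is a mixture, so marker lists call no cell type. Lists were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the lists), which compares a list with all other genes. With the preset its p-values rest on the spread between genes and on that correlation, so they do not measure the spread between samples. Camera with an estimated correlation called 0 lists in every comparison (smallest adjusted p = 0.127, 0.126 and 0.378), so each call by camera depends on the preset. The test fry, which uses no preset, called 5, 3 and 0 lists, named below. Hepatocyte and skeletal muscle lists were added after seeing the data and were used only as values. Other cardiac genes, listed before their values were seen, were used in 1 test, without the filter on low values.

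The naming rule took, per comparison, the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap; where none passed, the 5 with the smallest p in each direction; Dusp1 always; and up to 2 rises and 2 falls per list. Of the list genes, the text gives the 2 with the largest change in the direction of each list that passed, a narrowing made after the data were seen, and sign changes under the alternatives were counted over all that the rule selected. Genes named outside it are said to be so.

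Replicate numbers in the titles recur across groups. In the check for pairing, deviations from group means correlated above 0.1 for all 7 pairs of arrays with the same number (0.11 to 0.72), while those with different numbers ranged from -0.59 to 0.40. This was taken only as a hint from the data that the numbers pair the arrays, since the labels name no shared batch or day. The main model held no replicate block, which was run as an alternative. This hint is weak beyond the first prone and supine arrays, whose 0.72 alone exceeded every pair with different numbers. Deviations cancel out within a group, so the correlations are not independent and the controls mirror each other. Supine replicate 2 correlated at 0.40 with prone replicate 3 and at 0.29 with prone replicate 2. Where the block changed a call it is given with the result, for probe sets as a count.

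The model was tested on simulated data for prone against control with 16896 probe sets, 200 of them changed, over 20 runs. It recovered 0.37% of changes of 1 log2 unit, 16.2% of 2 and 81.5% of 4, with 3.65 false calls per run. The list test, on 10240 genes simulated with independent noise, found a heat shock list shifted by 1 log2 unit in 20 of 20 runs. It called 4 of 540 tests of other lists. Genes of a list did not vary together in these runs, so the runs cannot show how often the preset calls correlated lists wrongly. Alternatives covered the filter, another quantile normalization, centring, an intensity trend, a robust prior, array weights, fits to only the groups compared, the replicate block, a 2-fold threshold, other list tests, other choices of probe set and leaving out each array. A fit without replicate 1 of both positions and a fit with the beta-actin 3′ minus 5′ signal as a covariate were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.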

Results

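Gene expression was measured in the dorsal-caudal part of the lung of male Sprague-Dawley rats with Affymetrix rat expression arrays, on which a gene is read by 1 or more probe sets. The rats weighed 340 to 400 g. 3 samples came from ventilation in the prone and 3 in the supine position, at a high tidal volume of 18 mL per kg body weight, with no positive end-expiratory pressure (0 cmH2O) and 40 breaths per minute, for up to 3 hours. 2 samples were not ventilated. The titles call each sample a biological replicate. The 8 arrays thus form groups of 2, 3 and 3, and this number limits the precision of every value below. The series title names MAP kinase phosphatase-1, the product of Dusp1, which switches off stress-activated MAP kinases, and regional effects of injurious ventilation. The arrays bear on what ventilation changed in this region and on whether body position altered it.

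The table held 20242 probe sets, and 16896 of them were tested. Of these, 13155 carried 1 gene symbol and stood for 10240 named genes, 319 carried several symbols and 3422 none. Median log2 values lay between 7.77 and 7.95 on the 8 arrays. Supine replicate 3 stood apart in RNA quality. Its 3′ beta-actin probe set exceeded the 5′ one by 9.10 on the log2 scale, against 3.16 to 4.64 on the other arrays, and the same difference for GAPDH was 8.41 against 0.70 to 1.92. A wide gap between 3′ and 5′ signal is the usual sign of degraded RNA on this type of array.

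**Figure D1:**
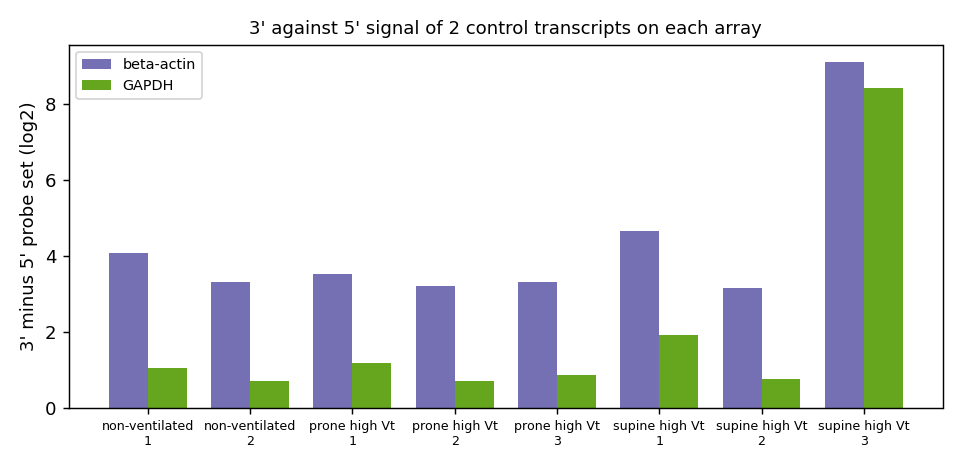
Difference between the 3′ and 5′ control probe sets of beta-actin and GAPDH (log2, vertical axis) on each of the 8 arrays, 1 pair of bars per array. Supine replicate 3 reaches 9.10 and 8.41, while no other array exceeds 4.64 and 1.92.

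Prone ventilation against no ventilation was marked by stress and inflammatory transcripts. All 13 tested heat shock genes were higher, with a median of 3.15 log2 units, and every prone array lay above both non-ventilated arrays for each of them. Hspa1a, an inducible chaperone of the Hsp70 family, was 4.69 ± 0.83 higher (log2, SE; 15.01 ± 0.35 in 3 prone lungs against 10.33 ± 0.86 in 2 controls, SD), and its co-chaperone Bag3 was 4.06 ± 0.91 higher. The list rose by limma's camera with a preset correlation between genes (adjusted p = 1.89e-14), and all 13 genes passed when adjusted over the list alone, although none passed over all probe sets. With a correlation estimated from the data the heat shock list had adjusted p = 0.284. The immediate early transcription factors, which respond within hours to stress signals, rose too (median 1.38, adjusted p = 3.73e-07, or adjusted p = 0.33 with an estimated correlation). Of 25 tested, 11 were higher and 1 lower when adjusted over the list alone. Nr4a3 was 7.04 ± 1.76 higher (adjusted p = 0.0213 over the list alone) and Atf3 4.75 ± 0.86 higher (adjusted p = 0.0174).

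Markers of inflammation, endoplasmic reticulum stress and oxidant defence moved the same way in the prone lungs. The cytokine and chemokine list rose (median 1.88, adjusted p = 0.00114, or adjusted p = 0.484 with an estimated correlation), with Il6 at 7.89 ± 2.92 and the monocyte attractant Ccl7 at 5.75 ± 2.09 above controls. Only 1 of its 25 members passed when adjusted over the list alone. Prone replicate 1 carried the list, with a median of 4.33 against 0.24 and 0.04 in the other prone lungs, and without that array the list median was 0.11 (adjusted p = 0.114), and without the first prone and supine arrays adjusted p was 0.229. Without prone replicate 3 the median was 3.00. NF-kappaB targets and feedback genes rose (median 1.34, adjusted p = 1e-05, or adjusted p = 0.453 with an estimated correlation). The nuclear IkappaB protein gene Bcl3 (4.65 ± 0.99, adjusted p = 0.0325) was the 1 of 18 that passed over the list alone, while the adhesion molecule Selp stood at 3.45 ± 2.08, or 2.22 without prone replicate 1. The unfolded protein response rose (median 1.16, adjusted p = 5.43e-07, or adjusted p = 0.365 with an estimated correlation), with 2 of 16 genes past the list alone. Its largest differences did not pass. Chac1 averaged 9.12 ± 0.81 in prone against 4.12 ± 0.67 in control lungs (SD), and Trib3 stood at 1.88 ± 0.71. The glucocorticoid response rose (median 1.62, adjusted p = 5.88e-07, or adjusted p = 0.127 with an estimated correlation), with 4 of 15 genes past the list alone, among them Il1r2, a decoy receptor for interleukin-1 (5.63 ± 1.05), and the metallothionein Mt2A (12.11 ± 2.22 against 7.11 ± 0.19, SD). The NRF2 oxidant response rose (median 0.60, adjusted p = 0.000142, or adjusted p = 0.127 with an estimated correlation), and the 2 of 11 genes past the list alone were Hmox1, which degrades haem (4.36 ± 0.98), and Srxn1, which restores peroxiredoxins (4.33 ± 0.78).

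Several cell type lists shifted between prone and control lungs. Neutrophil markers rose (median 2.13, adjusted p = 1.07e-05, or adjusted p = 0.453 with an estimated correlation), with 6 of 11 past the list alone, including Il1r2 and the gelatinase Mmp9 (4.73 ± 0.86). Lymphocyte markers fell: all 15 were lower (median -2.33, adjusted p = 3.36e-06, or adjusted p = 0.396 with an estimated correlation) and 8 passed over the list alone. The cytotoxic cell genes Nkg7 and Gzma stood at -4.14 ± 1.67 and -4.08 ± 2.02 and did not pass. Gzma read 9.49 on prone replicate 1, above its control mean of 9.02, and 3.22 and 2.11 on the other prone arrays. Its difference was -6.35 without prone replicate 1 and -2.66 without prone replicate 3. Mesothelial markers, genes of the cells that cover the lung surface, fell (median -2.35, adjusted p = 3.47e-05, or adjusted p = 0.239 with an estimated correlation). All 7 were lower and 4 passed over the list alone, among them the transcription factor Bnc1 (-3.72 ± 0.28) and the uroplakin Upk1b (-3.09 ± 1.00). Alveolar type 1 markers fell (median -0.85, adjusted p = 0.0132, or adjusted p = 0.396 with an estimated correlation) with 9 of 10 lower and 0 past the list alone. Akap5 stood at -1.43 ± 0.89 (-0.86 without prone replicate 1) and the water channel Aqp5 at -1.35 ± 0.52. Without the first prone and supine arrays, a fit added after seeing the data, adjusted p was 0.0623. Erythroid markers rose (median 1.00 over 4 genes, adjusted p = 0.0132, or adjusted p = 0.453 with an estimated correlation). The haem synthesis gene Alas2 (3.41 ± 0.60) passed over the list alone, and Rhd stood at 1.55 ± 0.62. With the replicate number as a block adjusted p was 0.079 and at a filter of log2 7 it was 0.0559, and without prone replicate 1 the median was 1.62. Smooth muscle and pericyte markers rose (median 0.74, adjusted p = 0.0132, or adjusted p = 0.484 with an estimated correlation; 0 of 11 past the list alone), with Cnn1 at 2.52 ± 0.64 and Pdgfrb at 1.24 ± 0.49. Cardiac muscle markers rose (median 2.40, adjusted p = 0.0319, or adjusted p = 0.484 with an estimated correlation; 0 of 6 past the list alone), with Myl4 at 3.11 ± 1.63 and Tnni3 at 2.75 ± 1.61. Without prone replicate 2 these were 1.74 and 1.20, and without prone replicate 3 Myl4 was 4.69. With the replicate block adjusted p was 0.0594 for the cardiac list, which lost its call in 7 of 23 alternatives, among them a filter of log2 7, centred arrays and a fit to only the compared groups (adjusted p = 0.106, 0.0665 and 0.0517). Both muscle lists rested on prone replicate 2, whose cardiac median was 5.85 above controls. Without it the medians were 0.16 for cardiac (adjusted p = 0.309) and 0.34 for smooth muscle markers (adjusted p = 0.111), and without prone replicate 3 the smooth muscle median was 0.48. For each list that passed against controls, in prone and in supine lungs, the estimated correlation gave the highest adjusted p of the 23 alternatives run.

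Over all probe sets, 9 passed in the prone comparison (limma, Benjamini-Hochberg), 1 higher and 8 lower. They included Scel, which encodes sciellin (-4.58 ± 0.35, adjusted p = 0.0172), Tspyl4 (-4.30 ± 0.38, adjusted p = 0.0221), Bnc1 (adjusted p = 0.0172) and Grtp1 (-3.40 ± 0.35, adjusted p = 0.0336). The other calls were 2 probe sets without a gene symbol and second probe sets of Pnkd, Lrrn4 and Arhgap1, named after their values were seen. Scel, Tspyl4 and Bnc1 averaged 2.94, 2.01 and 3.03 on the prone arrays, the low end of the scale, where the size of a fall is uncertain. Scel had an SD of 0.04 on the prone arrays against 0.74 on the controls. The model takes 1 spread for all groups, so the adjusted p of Scel is uncertain too. At a filter of log2 7, or with an intensity trend, 0 probe sets passed. At an unadjusted p under 0.05 there were 2989 probe sets, 17.7% of those tested (1296 higher, 1693 lower), and 48.6% had groups that did not overlap, where chance gives 20%. The median change over all probe sets was -0.12, and centring the arrays on their medians moved it to -0.005. With that centring 11 passed, 3 of them higher, and after another quantile normalization 13 passed, 4 of them higher. The count of 9 was unstable. It was 0 with the replicate number as a block, without either control array and without prone replicate 2 or 3. It was 115 without prone replicate 1, and 5, 65 and 90 without supine replicates 1, 2 and 3, which enter only through the shared estimate of the spread.

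Supine ventilation against no ventilation gave many of the same groups of genes. Neutrophil markers rose (median 2.20, all 11 higher, 5 past the list alone; adjusted p = 2.56e-05, or adjusted p = 0.531 with an estimated correlation), with Il1r2 at 5.69 ± 1.05 and Mmp9 at 4.26 ± 0.86. The NRF2 oxidant response rose (median 1.11, 4 of 11 past the list alone; adjusted p = 0.000201, or adjusted p = 0.126 with an estimated correlation), led by Srxn1 (5.28 ± 0.78) and the cystine transporter Slc7a11 (3.06 ± 0.78). The glucocorticoid response rose (median 1.39, 4 of 15 past the list alone; adjusted p = 4.79e-05, or adjusted p = 0.167 with an estimated correlation), with Mt2A at 5.97 ± 1.51. Its median was 0.78 without the degraded supine replicate 3 and 0.88 without control replicate 1. All 13 heat shock genes were higher (median 1.22), 3 of them past the list alone, and the list rose (adjusted p = 4.46e-06, or adjusted p = 0.531 with an estimated correlation). Hspa1a was 3.03 ± 0.83 and Hsph1, a large heat shock chaperone, 2.60 ± 0.61 higher.

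The inflammatory lists rose in supine lungs as well. Cytokines and chemokines had a median of 1.63 (0 of 25 past the list alone; adjusted p = 0.00349, or adjusted p = 0.606 with an estimated correlation), with Il6 at 6.58 ± 2.92 and Ccl7 at 5.94 ± 2.09. The cytokine medians were 3.21, 0.08 and 1.41 on supine replicates 1 to 3, against -0.17 and 0.17 on the control arrays. Without supine replicate 1 the list median was 0.56 (adjusted p = 0.0464), and without supine replicate 2 it was 2.76. NF-kappaB targets and feedback genes had a median of 1.20 (adjusted p = 0.000126, or adjusted p = 0.561 with an estimated correlation), with Bcl3 (4.70 ± 0.99) alone of 18 past the list and Selp at 3.77 ± 2.08, or 2.45 without supine replicate 1 and 5.87 without supine replicate 2. Their medians were 2.01, 0.17 and 1.26 on supine replicates 1 to 3, against -0.12 and 0.12 on the control arrays, and without supine replicate 1 the list median was 0.71 (adjusted p = 0.00233). The unfolded protein response rose (median 0.82, 0 of 16 past the list alone; adjusted p = 0.000478, or adjusted p = 0.531 with an estimated correlation), with Chac1 at 2.95 ± 1.68 and Creld2 at 1.91 ± 0.70. Chac1 read 6.97, 3.72 and 10.53 on supine replicates 1 to 3, against a control mean of 4.12, and its difference was 1.22 without the degraded replicate 3 and 4.63 without replicate 2. Matrix remodelling and coagulation genes rose (median 1.18, 1 higher and 1 lower of 18 past the list alone; adjusted p = 0.0182, or adjusted p = 0.46 with an estimated correlation), with the protease Adamts4 at 5.59 ± 2.48 and the protease inhibitor Tfpi2 at 5.09 ± 2.25. Without control replicate 1 the adjusted p of this list was 0.0577, and without the degraded supine replicate 3 its median was 0.70 (adjusted p = 0.0278). With the mean of each gene's probe sets adjusted p was 0.0604. Cell cycle genes rose (median 1.02, 3 of 13 past the list alone; adjusted p = 0.00109, or adjusted p = 0.46 with an estimated correlation), with the mitotic kinase Aurkb at 2.64 ± 1.12 and cyclin Ccnb2 2.13 ± 0.28 higher. Without supine replicate 2 the cell cycle median was 0.58 (adjusted p = 0.019) and Aurkb stood at 1.64. The immediate early list had a median of 0.50 (0 of 25 past the list alone; adjusted p = 0.0413, or adjusted p = 0.606 with an estimated correlation), with Fosl1 at 4.93 ± 1.71 and Nr4a3 at 4.06 ± 1.76, or 2.09 without supine replicate 3. That call was lost in 14 of 23 alternatives. It ended with the replicate block (adjusted p = 0.125) and without the degraded supine replicate 3 (median 0.30, adjusted p = 0.183), while without supine replicate 2 the median was 0.78 (adjusted p = 0.0014). Without control replicate 2, prone replicate 1 or supine replicate 1 adjusted p was 0.104, 0.0621 and 0.0672. It was 0.0565 with centred arrays, 0.0576 after another quantile normalization and 0.0565 with camera on ranks.

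Mesothelial markers fell in supine lungs (median -3.01, all 7 lower on every supine array than on both controls, 6 past the list alone; adjusted p = 1.61e-07, or adjusted p = 0.126 with an estimated correlation). Upk1b averaged 5.14 ± 1.33 in supine against 10.14 ± 0.36 in control lungs (SD), and Bnc1 (-3.79 ± 0.28, adjusted p = 0.0164) and the neuronal glycoprotein gene Gpm6a (-3.69 ± 0.39, adjusted p = 0.0392) passed over all probe sets. Lymphocyte markers fell (median -1.51, 14 of 15 lower and 0 past the list alone; adjusted p = 0.00122, or adjusted p = 0.561 with an estimated correlation), with Cd79b at -3.80 ± 1.30 and Cd3g at -1.92 ± 0.82. Without control replicate 1 the median was -0.98 (adjusted p = 0.0577). Alveolar type 1 markers fell (median -0.77, 0 of 10 past the list alone; adjusted p = 0.00762, or adjusted p = 0.46 with an estimated correlation), with Akap5 at -2.15 ± 0.89 and Aqp5 at -1.70 ± 0.52. Without the first prone and supine arrays adjusted p was 0.0513.

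In all, 9 probe sets passed in the supine comparison, 1 higher and 8 lower. Scel (-4.63 ± 0.35, adjusted p = 0.0164) and Tspyl4 (-3.90 ± 0.38, adjusted p = 0.0392) were among them. They averaged 2.89 and 2.41 on the supine arrays, again the low end of the scale. Second probe sets of Lrrn4, Arhgap1 and Cyp26b1, an enzyme that degrades retinoic acid, were named after their values were seen, and 2 calls had no gene symbol. There were 2573 probe sets (15.2%) at an unadjusted p under 0.05, and 41.8% had groups that did not overlap, where chance gives 20%. The count of 9 fell to 0 with the replicate block and without any single array other than supine replicate 2, whose removal gave 153. Without supine replicates 1, 2 and 3 there were 2520, 4016 and 1709 probe sets at an unadjusted p under 0.05, the last without the degraded array.

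**Figure D2:**
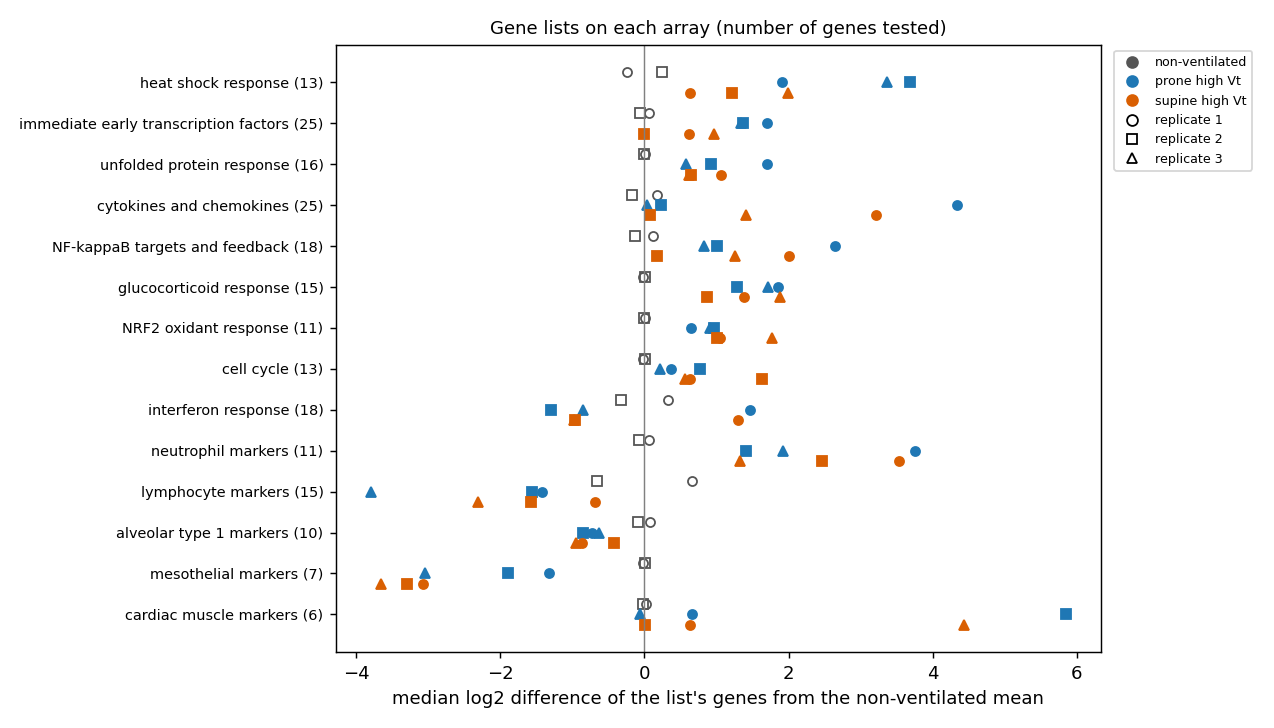
Median log2 difference of the genes of 14 lists from the non-ventilated mean (horizontal axis), 1 symbol per array; colours mark the 3 groups, shapes the replicate numbers, and the number of genes tested stands in brackets. Heat shock medians lie between 1.91 and 3.68 on prone and between 0.63 and 2.00 on supine arrays, and mesothelial medians lie between -3.65 and -1.33 on the ventilated arrays.

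The difference between positions was tested directly as supine against prone, which equals the difference of the ventilation effects because both use the same controls. The titles of the supine samples read SVt where those of the prone samples read HVt, while the condition label names a high tidal volume for both. If SVt stood for another tidal volume, position and tidal volume could not be told apart here. The heat shock response was lower in supine lungs: all 13 genes were lower, with a median of -1.32, and 3 passed over the list alone. Hspb8, a small heat shock protein, was lower by 2.40 (log2 fold change -2.40 ± 0.56, adjusted p = 0.0191 over the list alone), and Bag3 stood at -2.29 ± 0.81. The list fell by camera with the preset correlation (adjusted p = 1.18e-13), but adjusted p was 0.378 with an estimated correlation. Over the 23 alternatives adjusted p ranged from 2.2e-21 to 0.409. Without the degraded supine replicate 3 the median was -1.81. The 5S ribosomal RNA control probe set differed between the same arrays. It read 4.41, 10.35 and 9.88 on prone and 5.23, 5.17 and 8.75 on supine replicates 1 to 3, where the heat shock medians were 1.91, 3.68 and 3.37 on prone and 0.63, 1.22 and 2.00 on supine arrays. On the control arrays it read 5.13 and 7.51. Immediate early transcription factors fell (median -0.87, 20 of 25 lower, 0 past the list alone; adjusted p = 2.49e-08, or adjusted p = 0.378 with an estimated correlation), with the orphan nuclear receptors Nr4a1 at -3.35 ± 0.73 and Nr4a3 at -2.98 ± 1.58. Nr4a3 read 6.01, 3.56 and 10.68 on supine replicates 1 to 3, the last above every prone array, and its difference was -4.95 without supine replicate 3 and -1.39 without supine replicate 2. The immediate early median was -0.50 without prone replicate 1 (adjusted p = 0.00531) and -0.42 without supine replicate 2 (adjusted p = 0.012). Stretch and YAP/TAZ targets fell (median -0.14, adjusted p = 0.00458, or adjusted p = 0.378 with an estimated correlation), with the matricellular gene Ccn1 (-3.28 ± 0.65) alone of 16 past the list and the growth factor gene Hbegf at -1.91 ± 0.54. Without prone replicate 1 or supine replicate 1 adjusted p was 0.108 or 0.0647. The call also ended with camera on ranks (adjusted p = 0.0814) and without the first prone and supine arrays (adjusted p = 0.185), and the mean of the list was -0.48. The stretch median was -0.05 without prone replicate 1, -0.26 without prone replicate 2, -0.35 without prone replicate 3 and -0.25 without supine replicate 2. The unfolded protein response fell (median -0.28, 0 of 16 past the list alone; adjusted p = 0.00274, or adjusted p = 0.833 with an estimated correlation), with Chac1 at -2.05 ± 1.51 and Trib3 at -1.10 ± 0.64. Without supine replicate 3 these were -3.78 and -1.72, and without supine replicate 2 they were -0.37 and -0.38. The call ended without prone replicate 1 (median -0.05, adjusted p = 0.655) or supine replicate 2 (adjusted p = 0.147), and the median was -0.59 without prone replicate 3 and -0.15 without supine replicate 3. With array weights adjusted p was 0.154 and without the first prone and supine arrays 0.43. Over the alternatives the highest adjusted p of each of the 10 lists that passed between positions lay between 0.409 and 0.86.

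Dusp1 itself was highly expressed in all lungs. Its brighter probe set averaged 13.78 ± 0.48 in controls, 14.15 ± 0.17 in prone and 13.32 ± 0.36 in supine lungs (SD; n = 2, 3 and 3). All 3 supine values lay below all 3 prone values, a log2 fold change of -0.83 ± 0.31 that did not pass (adjusted p = 0.942, and 0.346 to 1 over the alternatives). Against controls it stood at 0.37 ± 0.35 in prone (adjusted p = 0.615) and -0.46 ± 0.35 in supine lungs (adjusted p = 0.527). Without control replicate 1 these were 0.71 and -0.12, and without control replicate 2 they were 0.03 and -0.80. The second probe set read 7.92 and 7.81 on the controls and 7.61 to 9.19 on the prone arrays. On supine replicates 1 to 3 it read 2.62, 7.17 and 2.60. Between positions its log2 fold change was -4.37 ± 1.18 (limma, adjusted p = 0.942). Values of 2.62 and 2.60 are at the low end of the scale, where a fold is uncertain. They fell on the 2 arrays with the widest 3′ minus 5′ gaps (beta-actin 4.64 and 9.10, GAPDH 1.92 and 8.41). Control replicate 1 had the next widest beta-actin gap, 4.06, and read 7.92. Whether RNA quality lowered the supine values was not tested. The list of MAP kinase phosphatases as a whole was not shifted in any comparison (adjusted p = 0.994, 0.815 and 0.578 for prone and supine against controls and supine against prone), nor was the MAP kinase cascade (0.207, 0.0749 and 0.54).

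**Figure D3:**
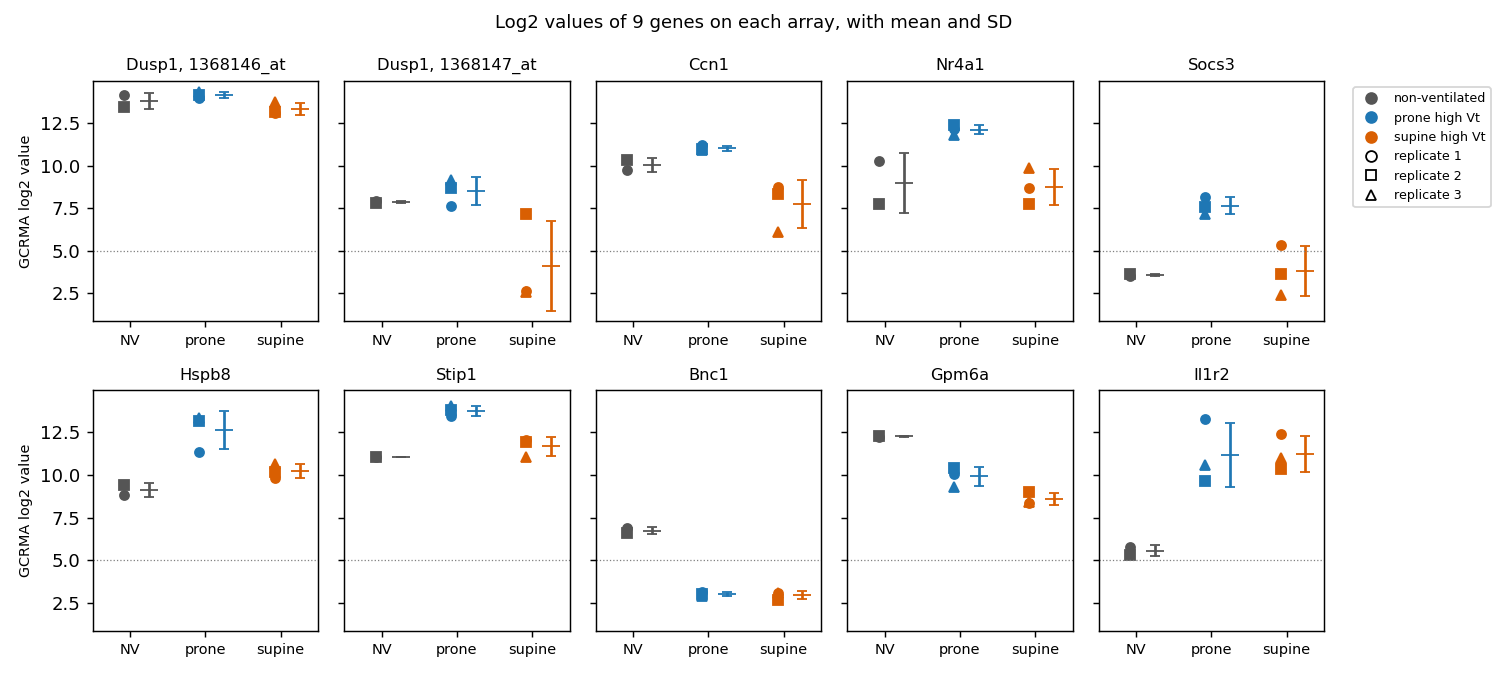
GCRMA log2 values (vertical axis) of 9 genes, with 2 probe sets for Dusp1, on each of the 8 arrays; symbols are arrays, shapes replicate numbers, bars the group mean and SD, and the dotted line the filter level of 5. Ccn1, Nr4a1, Socs3, Hspb8 and Stip1 are lower on all 3 supine than on all 3 prone arrays, and Bnc1 lies near 3 on all ventilated arrays.

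Cell type lists also differed between positions. Mesothelial markers were lower in supine lungs (median -1.34, 5 of 7 lower and 1 past the list alone; adjusted p = 0.00274, or adjusted p = 0.378 with an estimated correlation), with Upk1b at -1.91 ± 0.90 and the surface protein Msln at -1.58 ± 0.55. Upk1b was -1.03 without prone replicate 1 and Msln -0.98 without prone replicate 2. The call ended without prone replicate 1 (median -0.54, adjusted p = 0.108), and without supine replicate 2 the median was -0.86 (adjusted p = 0.0383). Erythroid markers were lower (median -1.07, 0 of 4 past the list alone; adjusted p = 0.00377, or adjusted p = 0.614 with an estimated correlation), with Ahsp at -1.48 ± 1.20 and Alas2 at -1.15 ± 0.54. Ahsp lay between -2.67 and -0.68 without single arrays, at -2.44 and -0.68 without prone replicates 1 and 3 and at -0.73 and -2.67 without supine replicates 1 and 3, and Alas2 was -0.70 without supine replicate 1. Without supine replicate 1 or 2 adjusted p was 0.146 or 0.0696, and the median was -0.72 without supine replicate 1 and -0.65 without prone replicate 3. The erythroid medians also ran beside the 5S signal, at 0.22, 1.28 and 2.00 on prone and -0.20, 0.29 and 1.02 on supine replicates 1 to 3. Airway epithelium markers were lower (median -0.42, all 12 lower and 0 past the list alone; adjusted p = 0.00934, or adjusted p = 0.833 with an estimated correlation). Bpifa1 stood at -2.93 ± 2.58, from 13.71 on prone replicate 2 alone, and turned to 0.48 without it and to -4.79 and -4.48 without prone replicates 1 and 3, and the cilia regulator Foxj1 stood at -1.35 ± 0.57. Without prone replicate 2 the median of the list turned to 0.30 (adjusted p = 0.476). The call also ended without supine replicate 1 or 3 (medians -0.23 and -0.20, adjusted p = 0.171 and 0.122). The airway median was -1.23 without prone replicate 1, -0.66 without prone replicate 3 and -1.28 without supine replicate 2. With the beta-actin covariate it was -0.03 (adjusted p = 0.406). Smooth muscle and pericyte markers were lower (median -0.30, 0 of 11 past the list alone; adjusted p = 0.0348, or adjusted p = 0.833 with an estimated correlation), with Des at -1.16 ± 0.65 and Actg2 at -0.74 ± 0.59. Without prone replicate 2 these were -0.76 and -0.47, without supine replicate 3 they were -0.44 and -0.12, and without supine replicate 2 Actg2 was -1.32. It was lost in 8 of 23 alternatives, among them the fits without prone replicate 2, supine replicate 1 and supine replicate 3 (medians 0.06, -0.14 and -0.16, adjusted p = 0.747, 0.287 and 0.322), so the median turned without prone replicate 2. Without prone replicate 1 or supine replicate 2 it was -0.68 or -0.56. At a filter of log2 7, with the mean of each gene's probe sets and with the covariate adjusted p was 0.0622, 0.0603 and 0.86. Cell cycle genes were higher (median 0.48, all 13 higher, 0 past the list alone; adjusted p = 0.00197, or adjusted p = 0.445 with an estimated correlation), with Aurkb at 1.25 ± 1.00 and cyclin Ccna2 at 1.13 ± 0.28. Aurkb was 0.71 and 2.00 without prone replicates 1 and 2 and 2.08 and 0.25 without supine replicates 1 and 2. The call ended without prone replicate 1 or supine replicate 2 (adjusted p = 0.108 and 0.161), and without the latter the median was 0.25. Lymphocyte markers were higher (median 0.92, 0 of 15 past the list alone; adjusted p = 0.00377, or adjusted p = 0.833 with an estimated correlation), with the granzymes Gzma at 3.71 ± 1.81 and Gzmb at 2.79 ± 1.45. Without prone replicate 1 these were 5.98 and 4.56, and without prone replicate 3 they were 2.29 and 1.47. The call ended without prone replicate 3 or supine replicate 1 (medians 0.37 and 0.45, adjusted p = 0.204 and 0.11) and with array weights (adjusted p = 0.0957).

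No probe set passed between positions (limma, 0 of 16896, smallest adjusted p = 0.942), with 691 (4.09%) at an unadjusted p under 0.05, and 5.89% had groups that did not overlap, where chance gives 10%. The 691 depended on single arrays, from 270 without prone replicate 3 to 2265 without prone replicate 1. With the replicate block it was 1256. The genes with the smallest p values did not pass. Lower in supine lungs were the Hsp70-Hsp90 organizing protein gene Stip1 (-2.09 ± 0.34), the cytokine signalling inhibitor Socs3 (-3.85 ± 0.68), Utp23 (-1.70 ± 0.33), Dedd2 (-2.25 ± 0.44) and Ccn1. Higher were the mitotic kinesin Kif15 (1.59 ± 0.26), Prr5l (1.86 ± 0.41), the protease Adamts15 (2.41 ± 0.55), the histone demethylase Kdm5c (1.19 ± 0.28) and Eri2 (1.68 ± 0.42). A second probe set of Kdm5c did not rise and stood at -0.20 ± 0.24. Without prone replicate 1 the count of probe sets that passed was 3, and without prone replicate 2 or supine replicate 2 it was 1. Without supine replicate 1, 6 lists passed between positions, and 5 of the 10 above were lost.

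The effects of prone and supine ventilation ran together across probe sets, which are not independent replicates (correlation 0.81, same sign in 81.4%). Unchanged groups of independent arrays simulated against the same 2 controls gave 0.60 and 70.5%. In simulations added after seeing the data, arrays of 1 replicate number deviated together. With the measured correlations of the prone and supine arrays of each number (0.72, 0.29 and 0.20) unchanged groups gave 0.76 and 77.5%, and with limma's consensus correlation over all arrays (0.29) they gave 0.63 and 71.7%. The covariance of the effects was 0.81, against 0.24 for independent arrays, a difference of 0.58. The simulated covariance was 0.30 with the measured and 0.19 with the consensus correlation. 6 probe sets passed in both comparisons in the same direction. The 100 simulations of each kind shared 0 calls. They held no effects, so few calls could arise in either comparison and this 0 does not weigh the overlap. Independent lists of that size would share 0.0038, a value that leaves out the shared controls. The 6 shared probe sets averaged 2.01 to 3.03 on the prone and 2.41 to 2.95 on the supine arrays, the low end of the scale. The controls are too few to be split, so part of each excess may come from them, and part from arrays of 1 number deviating together. The correlation was 0.65 without prone replicate 1.

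Several lists passed in only part of the comparisons. Between positions, adjusted p was 0.554 for cytokines and chemokines, 0.442 for NF-kappaB targets, 0.337 for the glucocorticoid response and 0.752 for the NRF2 response. It was 0.705 for neutrophil markers, 0.759 for alveolar type 1 markers, 0.588 for matrix remodelling and 0.538 for cardiac markers. In supine lungs against controls it was 0.33 for erythroid, 0.232 for smooth muscle, 0.106 for cardiac and 0.777 for airway markers, and 0.5 for stretch and YAP/TAZ targets. In prone lungs it was 0.241 for stretch and YAP/TAZ targets, 0.0507 for matrix remodelling, 0.0997 for cell cycle genes and 0.0694 for airway markers. With the replicate block, cell cycle genes and airway markers passed in prone lungs (adjusted p = 0.0472 and 0.0224). Matrix remodelling passed in prone lungs in 9 of 23 alternatives and airway markers in 7. Cell cycle genes also passed there with array weights (adjusted p = 0.0472). In supine lungs cardiac markers rose in a fit to only the compared groups and without prone replicate 2 (adjusted p = 0.0265 and 0.0253). Smooth muscle markers rose there with the beta-actin covariate and without supine replicate 3 (adjusted p = 0.00874 and 0.0451), and erythroid markers without the first prone and supine arrays (adjusted p = 0.0471).

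Between positions single arrays and the covariate made further lists pass, each lower in supine lungs. Without prone replicate 3 adjusted p was 0.000793 for cytokines, 0.00523 for NF-kappaB targets and 0.00405 for cardiac markers. Without prone replicate 2 it was 0.0357 for neutrophil markers and 0.0483 for the glucocorticoid response. NF-kappaB targets also passed without supine replicate 1 (adjusted p = 0.0172) and cardiac markers without supine replicate 3 (adjusted p = 0.0251). With the covariate adjusted p was 0.00501 for NF-kappaB targets, 0.0347 for the glucocorticoid response and 0.00931 for cardiac markers.

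Without an alternative setting, the remaining lists did not pass in any of the comparisons of prone with control, supine with control and supine with prone lungs, in that order. Adjusted p was 0.8, 0.5 and 0.588 for hypoxia and glycolysis, 0.994, 0.819 and 0.752 for the interferon response, and 0.204, 0.106 and 0.554 for ion and water transport. It was 0.0574, 0.154 and 0.578 for junction genes, 0.0728, 0.219 and 0.529 for alveolar type 2 markers, and 0.142, 0.058 and 0.578 for endothelial markers. It was 0.689, 0.427 and 0.554 for macrophage and monocyte markers and 0.994, 0.427 and 0.337 for fibroblast markers. Endothelial markers passed, lower in supine lungs, in 11 of 23 alternatives, the replicate block among them (adjusted p = 0.0316). They passed in prone lungs without prone replicate 3 (adjusted p = 0.0356). Ion and water transport genes fell without supine replicate 2, in supine lungs against controls (adjusted p = 0.019) and against prone lungs (adjusted p = 0.0485). Junction genes passed in 8 and alveolar type 2 markers in 6 alternatives in prone lungs, lower in each. Without the first prone and supine arrays alveolar type 2 markers were higher in supine than in prone lungs (adjusted p = 0.0263). Without prone replicate 1 the interferon list was lower in prone lungs (adjusted p = 0.0187) and higher in supine than in prone lungs (adjusted p = 0.00282). Without the first prone and supine arrays these were 0.00111 and 0.0474, and with array weights the second was 0.0477. Test direction differed in sign from the median or mean for some lists that did not pass. Against controls these were MAP kinase phosphatases, stretch targets, hypoxia and macrophage markers in prone lungs, and interferon and macrophage markers in supine lungs. Between positions they were cytokines, NF-kappaB targets, alveolar type 1, endothelial and neutrophil markers.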

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

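The fits without supine replicate 3, the fits with centred arrays and the counts over splits of the arrays were planned; the other tests in this part, and the use of those fits to weigh explanations, were chosen only after the results were seen. Because supine against prone tests the difference between the ventilation effects, the 10 lists past the preset-correlation threshold there were taken up for a closer look: heat shock (median -1.32), immediate early (-0.87), mesothelial (-1.34), unfolded protein (-0.28), erythroid (-1.07), stretch and YAP/TAZ (-0.14), airway epithelium (-0.42), smooth muscle and pericyte (-0.30), cell cycle (0.48) and lymphocyte (0.92) lists. Control probe sets outside the comparisons also exceeded both non-ventilated arrays by over 1 log2 unit. Beta-actin and GAPDH 3′ minus 5′ signals reached 9.10 and 8.41 on supine replicate 3. The mean of 18 spiked-in bacterial and phage control probe sets was 12.07 on prone replicate 2 and 12.46 on supine replicate 3, against at most 10.93 in controls. The 5S ribosomal RNA probe set read 10.35 and 9.88 on prone replicates 2 and 3 and 8.75 on supine replicate 3, against at most 7.51.

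Heat shock and immediate early genes were lower in supine than in prone lungs. Within the pairs of the same replicate number, the heat shock list differed by -1.30, -1.92 and -0.48. The immediate early list differed by -0.61, -1.47 and 0.03, so it was not lower in the pair of replicate 3. Degraded RNA on supine replicate 3 is argued against as the whole source, since the list medians without that array were -1.81 and -1.08. Splitting the 6 ventilated arrays 3 against 3 gives 10 splits, too few for a share under 0.05: 4 splits shifted 10 or more lists, the real one 10 and the highest other 12, and the 4 that part all 3 replicate pairs shifted 10, 10, 5 and 6, while the other 6 part 1 pair each. Another split gave a larger heat shock median (1.41 against 1.32) and another a larger immediate early median (0.99 against 0.87), the latter parting all 3 pairs. The 5S ribosomal RNA signal ran with the heat shock list, at 10.35, 9.88 and 8.75 on prone replicates 2 and 3 and supine replicate 3, which had the highest medians of the list (3.68, 3.37 and 2.00), and 4.41 to 5.23 on the other ventilated arrays, although in the pair of replicate 1 it read 4.41 and 5.23 and the list differed by -1.30. Chance in how the arrays fell into groups stays open, since other splits shifted as many lists. What raised this signal, and an effect of position, or of tidal volume if the SVt in the supine titles names another one, stay open too.

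For single probe sets between positions, the real split gave 0 calls and the highest other 1094. All 10 splits reach a count of 0, so this comparison cannot weigh chance, and the splits are too few for a share under 0.05. At an unadjusted p under 0.05, the 4 splits that keep the first prone and supine arrays together gave 5036, 3701, 1456 and 1012 probe sets (1094, 35, 0 and 0 calls), and the 6 that part them gave 237 to 691, the real one 691. Among the 4 that part all 3 replicate pairs the counts were 691, 237, 469 and 331. The far higher counts point to a structure of the samples other than position, which runs with the first prone and supine arrays. The split with 5036 set these and the degraded supine replicate 3 against the others, and the one with 3701 held supine replicate 2 in its place. With prone replicates 2 and 3 there the counts were 1456 and 1012. Those splits part prone replicate 2 from prone replicate 3, which correlated at 0.95 across probe sets. The splits with 5036 and 3701 keep these arrays together. Whether the degraded supine replicate 3 had a part was not tested.

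The median of the mesothelial markers was lower on each ventilated array than on both controls. Degraded RNA is argued against, because the median was -2.64 in supine lungs without replicate 3. Array medians lay only between 7.77 and 7.95, so the level the arrays were scaled to could account for little of the fall. Centring was bound to change the list little for the same reason and is no separate test. With arrays centred the list median was -2.24 in prone and -2.95 in supine lungs. Fewer mesothelial cells in the pieces taken would lower all markers alike, and an exact permutation test of unequal falls among the 5 members above log2 5 in every group gave p = 0.2 in prone and 0.1 in supine lungs, or 0.3 and 0.2 without Krt19, which other lung epithelium expresses, where 0.1 is the smallest p the arrays allow. Before this exact test an F test on the same falls had given p = 0.0303 and 0.00202, or 0.225 and 0.202 without Krt19, and a chi-square test p = 0.000673 and 4.85e-10, or 0.141 and 0.117; both lean on an approximation that so few arrays do not carry, so fewer cells and lower expression per cell cannot be told apart and an effect of ventilation stays open.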

How the results depend on the processing

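The fits without replicate 1 of both positions and with the beta-actin covariate were chosen after seeing the data; the other alternatives were planned. The cause of each change was not tested, except that fewer arrays or fewer probe sets enter where the setting says so. In prone lungs the 9 probe sets became 35 with no filter, 0 at a filter of log2 7, 0 with an intensity trend, 5724 with array weights, 119 with only the compared groups, 0 with the replicate block, 728 without the first prone and supine arrays, 125 with the covariate, and 0 to 115 when single arrays were left out. In supine lungs the 9 became 18, 0, 0, 36, 0, 0, 0 and 0 under these settings in that order, and 0 to 153 without single arrays. Between positions the count was 0 to 3 without single arrays and 0 otherwise. Where 1 control array is left out, the other is assumed to vary like the other groups. The lists that passed were 14, 13 and 10 for prone, supine and between positions. An estimated correlation gave 0, 0 and 0, and fry, which asks whether a list's genes move one way on balance, gave 5, 3 and 0. In prone lungs fry called the NRF2 (adjusted p = 0.00544), mesothelial (0.00596), glucocorticoid (0.012), heat shock (0.0302) and alveolar type 1 (0.0456) lists. In supine lungs it called the NRF2 and mesothelial (each 0.00187) and glucocorticoid (0.0177) lists. Between positions the count of lists was 6 to 12 without single arrays. The replicate block took away the call of 2, 1 and 0 lists and added 2, 1 and 0, all named above, and changed no other call of a list. Dusp1 between positions lay between -1.11 and -0.69 for its brighter probe set, was -2.60 as the mean of both, and never passed. The correlation of the ventilation effects became 0.72 with array weights, 0.74 without the first prone and supine arrays, and 0.65 to 0.85 without single arrays. Among 307 gene values the rule selected (278 at the filter of log2 7), 0 to 23 changed sign per setting, and of the 8 that had passed 0 did. Of the 90 gene values in the text that the naming rule gave, 24 moved by over 1.5 times without 1 array, each given above. Gene values chosen after they were seen were not counted there. Actg2 between positions became 0.11 with the covariate and Bpifa1 lay between -4.79 and 0.48 without single arrays. Signal over background limits what low values show, since a gene at the low end of the scale in one group has an uncertain fold.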

Other observations

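The median of 18 interferon response genes lay 1.46 and 1.30 log2 units above the control mean on prone and supine replicate 1, against -1.30 to -0.86 on the other ventilated arrays. All genes in this part were chosen after their values were seen. The interferon-induced chemokine Cxcl10 read 11.23 and 10.20 on those arrays, 3.03 and 3.09 on the other prone, 5.56 and 5.66 on the other supine, and 5.99 and 4.10 on the control arrays. Cxcl9 read 9.97 and 7.86 there and 2.75 to 3.13 on the other 6 arrays. The antimicrobial peptide gene Camp read 10.76 and 10.24, against 5.72 to 7.58. Prone and supine replicate 1 correlated at 0.96 across probe sets, which are not independent replicates, while the controls correlated at 0.98.

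The test in this paragraph was chosen after the values of the cardiac list and before those of the genes it uses were seen. Cardiac muscle markers were high on prone replicate 2 and supine replicate 3. The cardiac myosin heavy chain gene Myh6 read 9.87 and 8.87 there and 2.69 to 2.79 elsewhere. The atrial light chain Myl7 read 9.59 and 7.92 against 2.03 to 2.14. Of the 6 tested markers, 5 were higher on both arrays than on each of the other 6, which is how these arrays were picked and tests no source. Of these 6 markers, 3 reached log2 5 on at least 1 of the other arrays and 0 did on both controls. RNA of cardiac muscle cells in those pieces was tested as a hypothesis on 15 other cardiac genes, of which at least 50% were to be at log2 5 or above on both arrays and higher there than elsewhere if it was the source, and at most 25% if not. Tnnc1, Myom1 and Xirp1 were, 3 of 15 or 20%, against 2.7% of 11217 named genes. This lies under the lower bound, but the exact binomial 95% interval, 4.33% to 48.1%, reaches above it, and that interval was added after the value was seen. At any level, a count also added then, 9 of 15 were higher on both arrays, against 3.62% of all named genes. The source stays undecided.

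Of 7 hepatocyte markers, a list added after seeing the data, Alb and Ttr read 12.44 and 9.94 on supine replicate 3, and 8.27 and 5.15 on prone replicate 2, while Alb read 5.54 on prone replicate 3 and 2.25 to 2.36 on the other 5 arrays. The other members did not all run with them. On supine replicate 3 Hpx read 6.42 against 4.04 and 4.05 in controls and Rbp4 10.29 against 8.15 and 9.30, but Fgg read 10.76 against 10.90 and 11.45, Cyp2e1 9.70 against 9.46 and 10.49, and Serpina1 9.93 against 9.84 and 9.91. The airway secretory genes Bpifa1 and Muc5b read 13.71 and 11.44 on prone replicate 2. Skeletal muscle actin Acta1 stood at 4.32 ± 0.59 in prone and 3.78 ± 0.59 in supine lungs against controls (limma, adjusted p = 0.0686 and 0.133). The other members of the skeletal muscle list, also added after seeing the data, in prone and supine lungs, were Tnnt3 (1.99 ± 0.75 and 2.57 ± 0.75), Mybpc2 (0.67 ± 0.65 and 0.05 ± 0.65) and Myh1 (0.84 ± 0.36 and 0.38 ± 0.36). Single arrays weigh on the small differences. Mybpc2 read 6.89, 7.48 and 6.04 on prone replicates 1 to 3, against 6.13 on both controls. Myh1 read 10.98, 10.50 and 11.37 on supine replicates 1 to 3, against 10.39 and 10.75 on controls.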
